A study of Homo sapiens with 2 samples.

How the data were processed

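Ribosome footprint libraries were made from HEK293T cells and from transgenic cells derived from embryonic kidney, with 1 library each, using a commercial mammalian ribosome profiling kit per the labels' protocols. Per the submitters' processing notes, Bowtie was used and the genome build was GRCh38. The version of Bowtie, the trimming, the removal of ribosomal RNA, the read lengths kept, the treatment of reads that map to several places and the rule for assigning a read to a region are not given in the sources used here. Per the file headers, the authors deposited 4 columns of footprint counts, for the coding and the extended regions of each transcript in each library. The counts are whole numbers and are not normalized. How far an extended region reaches past the TAG codon is not given in the sources used here. Its length is therefore unknown, and densities per nucleotide were not computed. All 4 columns were used.

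Of 7180 gene identifiers, 3630 have several transcripts in the table, up to 30. Isoforms of a gene share sequence, and how footprints in shared sequence were assigned is not given in the sources used here. The column totals are sums over transcripts and may hold some footprints more than once, and transcripts that end in other stop codons are not in them. For values of single genes, the transcript with the highest mean scaled coding count was taken. Symbols are those the table pairs with each identifier, some of them old. Of the identifiers, 6077 carried a current symbol of the RefSeq annotation of GRCh38.p14, 549 were renamed through a unique synonym, 119 did not match, 34 were ambiguous and kept as given, and 401 had none. At the count minimum 12 symbols were shared by several identifiers. Gene coordinates are those of that annotation.

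The extended share was computed as extended counts over coding plus extended counts, in percent. Pooled shares are sums over sums. The interval of a ratio of pooled shares is the log-normal one for 2 binomial shares, and that of a single share is exact (Clopper-Pearson). The interval of a gene's ratio comes from the exact binomial interval of the split of its counts between libraries. All are 95% intervals and cover counting error only. Duplicate fragments and isoforms that share reads make them too narrow, and they leave out the variation between cultures and between library preparations, which 1 library per group cannot show. Where a gene had no extended count in HEK293T cells, a bound was computed against a floor of 3 counts per library. It takes the transgenic count as exact, so the lower limit of the exact interval is lower and is given beside it. Levels are counts scaled to the library's coding total (CPM), and log2 ratios were taken after adding a pseudocount of 1 CPM, which understates the ratio of low genes. Their intervals come from the counts without it. The minimum was 100 coding counts over both libraries together. Of the 15662 transcripts, 2408 had 0 in all 4 columns.

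No p-value was computed across genes, since neither group has a replicate. Percentiles among random gene sets describe these 2 libraries and do not test the cell lines. Transcripts at least 2-fold apart were counted by size. Gene lists written before the data were examined were described by the median log2 ratio of their measured members and its percentile among 10000 random lists of the same size, matched in 10 bins of mean level. A list needed 5 measured members. The named genes were chosen by a rule fixed at the same time: the 12 highest and 12 lowest log2 ratios, the 8 largest differences upward and 8 downward in extended share, the 10 most abundant genes of each library, up to 4 abundant members of each list and any member 2-fold apart, and ETF1, GSPT1 and ABCE1. Of the 8 largest differences upward, 1 is not reported here, and neither is 1 abundant list member. Classes of combined extended share with limits at 0.1%, 1%, 3% and 10%, and the 15 genes under 3% with the most extended counts in transgenic cells, were chosen after seeing the data.

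The functions were tested on simulated data. Counts for the 4086 genes were drawn with Poisson error around the observed levels and scaled by TMM, whereas the data were scaled to the coding total. Of 50 genes each changed 4-fold up, 3-fold up and 4-fold down, 100% passed the 2-fold rule. Of 50 changed 3-fold down, 98% passed, and of 3886 unchanged genes 0% did. A simulated ratio of extended shares of 4.96 was recovered as 4.93. There every gene had the same extended share within a library and independent counts, unlike in the data. The recovery therefore checks the function and not the pooled ratio of the data. Alternatives fixed in advance were other count minimums, pseudocounts and scalings (median of ratios, TMM and upper quartile), 1 transcript per gene, sums over transcripts, equal weights for transcripts and leaving out the transcripts with the most counts. Further list members named in the text are marked there as chosen after their values were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.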

Results

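Ribosome-protected fragments were sequenced from 2 human embryonic kidney cell populations, HEK293T, a widely used transformed embryonic kidney line, and a line called transgenic in the labels. Both were at passage 10 and both libraries are described as made in the presence of NAEK, an azide-bearing lysine analogue used in systems that decode the TAG (amber) stop codon as an amino acid. The labels do not name the transgene. Each population was represented by 1 library, so there was no replicate check on any difference below, and no p-values are given. The table covered 15662 transcripts of 7180 genes that end in TAG, each with a footprint count in its coding region and in an extended region, taken here as sequence past the TAG, since the table does not give its bounds. The HEK293T library held 5830437 coding and 197715 extended counts. The transgenic library held 8230225 coding and 397173 extended counts, so it was 1.41 times as deep over coding regions. A transcript was analysed further when its coding counts in both libraries together reached 100, which left 8365 transcripts of 4086 genes. Intervals are 95%; they and the floors cover counting error only, since duplicate reads are not independent molecules.

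The first comparison addressed where ribosomes lie along TAG-terminated transcripts in the 2 cell populations, and in particular how many footprints lie in the extended region. Extended footprints of several abundant genes were more frequent in transgenic cells. The extended share, extended counts over coding plus extended counts, of the cytoskeletal beta-actin gene ACTB was 0.801% in transgenic and 0.158% in HEK293T cells, 5.07 times as high (4.38 to 5.90). That of the translation elongation factor EEF2 was 0.506% against 0.0241%, and that of the beta-tubulin gene TUBB4B was 1.05% against 0.0217%. The ribosomal protein genes RPS10 and RPL23 had no extended count in either library, and the alpha-tubulin gene TUBA1A had similar shares of 3.75% and 4.08%.

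Over all transcripts, extended counts were found on 4305 of 8365 in transgenic cells and on 1853 in HEK293T cells. Thinned to the depth of the HEK293T library, the transgenic library would still have had extended counts on 3952 ± 16.1 transcripts (SD of the thinning). The pooled extended share was 3.42% in the transgenic library and 2.38% in the HEK293T library, a ratio of 1.43 (1.42 to 1.44). With 1 transcript per gene, so that isoforms that may share reads entered once, the shares were 3.69% and 2.61% and the ratio was 1.41 (1.40 to 1.42). Among the 4448 transcripts with any extended count, 3716 had the higher share in transgenic cells and 732 had the lower, so 83.5% were higher. Each transcript's extended counts were also dealt to the libraries by its own coding plus extended counts in each, so that shares were equal except for counting error. This gave 51.4% on average, and between 49.3% and 53.3% in 200 draws.

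The ratio of the shares depended on how large the extended share of a gene was, in classes that were set after the data were seen. In the 271 genes whose share over both libraries together was 10% or more, the shares were 41.3% in HEK293T and 47.1% in transgenic cells, a ratio of 1.14 (1.13 to 1.15). These genes held 91.8% of the HEK293T and 85.4% of the transgenic extended counts. In the 244 genes between 3% and 10% the ratio was 1.31 (1.27 to 1.35). In the 385 genes between 1% and 3% the shares were 0.571% and 2.37%, a ratio of 4.14 (3.91 to 4.39). In the 1015 genes between 0.1% and 1% they were 0.106% and 0.617%, a ratio of 5.81 (5.48 to 6.17), and in the 257 genes above 0 but under 0.1% the ratio was 6.57 (5.15 to 8.39). No extended count was found in either library for 1914 genes. Over all 3571 genes under 3%, including those, the share was 0.0729% in HEK293T and 0.368% in transgenic cells, 5.05 times as high (4.85 to 5.26). In percentage points the difference was largest at 10% or more, at 5.81, against 0.295 over all genes under 3%. It did not rise with every class, at 1.80 between 1% and 3% and 1.27 between 3% and 10%. A share cannot pass 100%, so large ratios are out of reach where the HEK293T share is large.

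**Figure D1:**
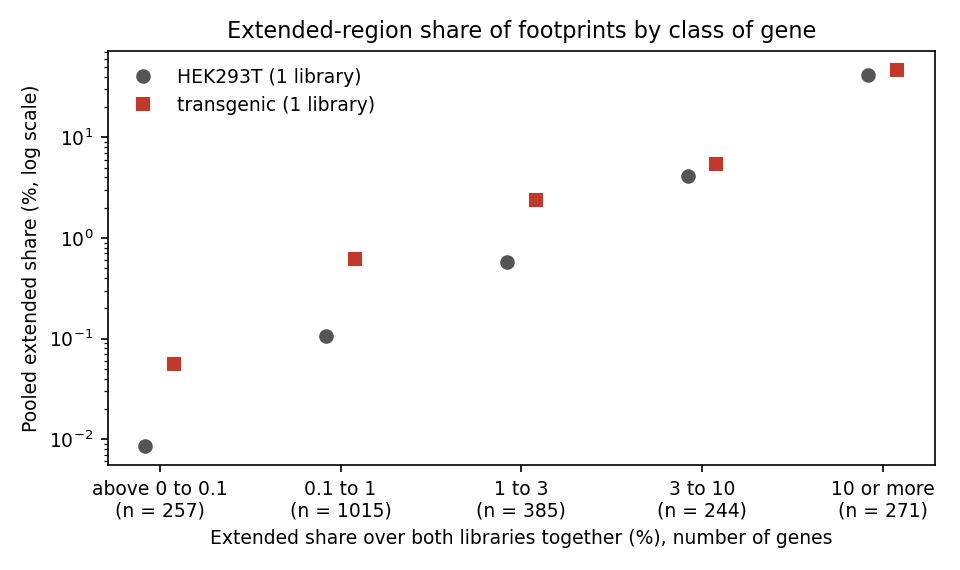
Pooled extended share of footprints (percent, log axis) in the HEK293T library (circles) and the transgenic library (squares), for genes grouped by their extended share over both libraries together; the number of genes is under each class. The squares lie 6.57, 5.81 and 4.14 times above the circles in the 3 lower classes and 1.31 and 1.14 times above them in the 2 upper classes.

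Of the 638 genes with 20 or more extended counts, 381 (59.7%) had shares within 2-fold of each other in the 2 libraries, and 136 (21.3%) had a share at least 8-fold higher in transgenic cells. A further 66 genes were at least 4-fold higher and 39 at least 2-fold, and 16 had a share more than 2-fold lower in transgenic cells. For the 78 genes without an extended count in HEK293T cells, the ratio was taken against a floor of 3 counts. Of these bounds, 35 were at 8-fold or more, 39 between 4-fold and 8-fold and 4 lower, and the ratios behind them may be in a higher class. Under a combined share of 3%, 46 of 231 genes were within 2-fold and 111 were at least 8-fold higher. At 10% or more, 248 of 267 were within 2-fold, but 61 of these 267 had a HEK293T share above 50%, where a 2-fold higher share is impossible.

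**Figure D2:**
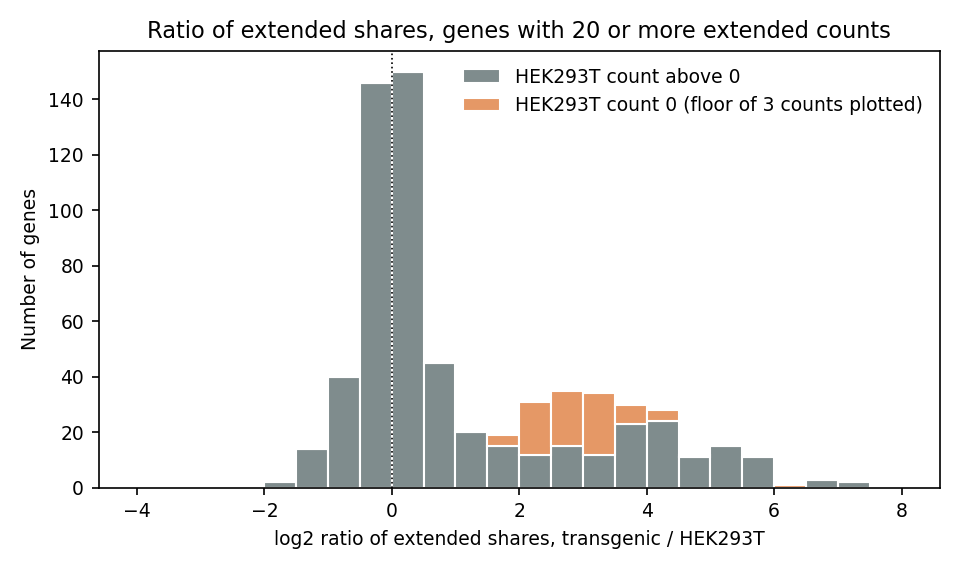
Number of genes by the log2 ratio of their extended shares, transgenic over HEK293T, for the 638 genes with 20 or more extended counts; orange bars are the 78 genes with no extended count in HEK293T cells, drawn against a floor of 3 counts. One peak of 381 genes lies within 2-fold of equal shares, and 202 genes form a broad shoulder at 4-fold or more.

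Several of the most abundant transcripts were among those with the larger differences. ACTB (ENSG00000075624, chromosome 7, 5527148 to 5530601 on GRCh38) had 204 extended counts beside 128921 coding counts in HEK293T cells and 1574 beside 194933 in transgenic cells. EEF2 (ENSG00000167658, chromosome 19, 3976056 to 3985463) had 15 and 467 extended counts, a 21-fold higher share in transgenic cells (12.6 to 37.8). TUBB4B (ENSG00000188229, chromosome 9, 137241287 to 137243707) had 7 and 349, a 48.5-fold higher share (23.3 to 122). The heat shock protein gene given as HSPA1A (ENSG00000204388) had 1 and 217, a ratio of 119 (21.2 to 4728). A second identifier with the same symbol (ENSG00000204389) had coding counts of 17652 and 31669, close to the 18553 and 33572 of the first, and no extended count. The HSPA1 genes are near-identical copies, so the split of reads between these identifiers is uncertain. The calcium-binding chaperone CALR had 0 and 10 extended counts, at least 2.39-fold higher against a floor of 3 counts per library, and the nucleolar protein NCL 0 and 9, at least 2.36-fold higher. The floor takes the transgenic count as exact. With its counting error the lower limits of the ratios are 1.61 and 1.56, and such a limit is given beside each named gene's bound below. TUBA1A had 931 and 1347, a ratio of 0.918 (0.844 to 0.999). RPS10 had none beside 40898 and 54417 coding counts, the ribosomal protein gene RPS7 had 2 and 0, and the histone gene H2BC18 had 0 and 1 beside 57479 and 76517.

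The 15 genes with the most extended counts in transgenic cells and a combined share under 3% were picked out after their values were seen. Choosing by the transgenic count favours genes that are higher in that library. The glyoxalase GLO1 (ENSG00000124767, chromosome 6, 38675925 to 38703145) had 3 extended counts in HEK293T and 403 in transgenic cells, shares of 0.0353% and 3.34% and a ratio of 94.6 (32.1 to 461). TALDO1, the transaldolase of the pentose phosphate pathway (chromosome 11, 747464 to 765012), had 3 and 377, a ratio of 91.5 (31.1 to 446). The complex I subunit NDUFS3 (chromosome 11, 47579074 to 47584562) had 0 and 273, at least 64.6-fold higher (lower limit 52.2). Among these 15 genes the smallest ratio was that of LYRM4, 83 and 138 extended counts, at 1.07 (0.809 to 1.42).

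**Figure D3:**
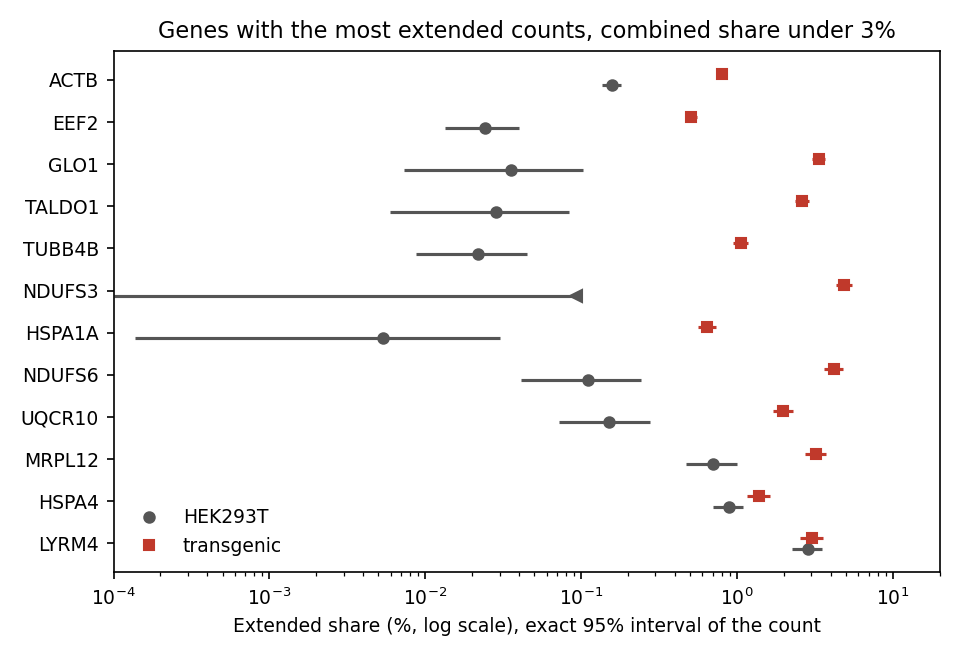
Extended share (percent, log axis) with its exact 95% interval in the HEK293T (circles) and transgenic (squares) library for the 12 genes with the most transgenic extended counts among those under a combined share of 3%; the triangle marks the upper bound of NDUFS3, which had a count of 0 in HEK293T cells. The intervals of the libraries are apart for every gene shown but LYRM4, at 2.84% and 3.03%.

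Of all 4086 genes 42.3% had a higher and 10.8% a lower extended share in transgenic cells. The counts below describe functional groups fixed before the data were examined, without a test of any group against other genes. For each group the extended counts in HEK293T and transgenic cells of its 4 most abundant measured members are given, except 1 member that is not reported here. Of 25 measured genes of oxidative phosphorylation, the mitochondrial respiratory chain, 14 had a higher extended share in transgenic cells, 4 a lower one and 7 no extended count, with 10 and 173 for UQCR10, 4 and 75 for NDUFA13, 0 and 2 for UQCRC1 and none for COX7A2. Of 18 heat shock and chaperone genes 12 were higher, none lower and 6 without counts, with 1 and 217 for HSPA1A, 2 and 35 for the co-chaperone FKBP4 and none for CCT2 and HSP90AB1. Of 28 mitochondrial ribosomal protein genes 18 were higher and 3 lower, with 30 and 159 for MRPL12, 0 and 5 for MRPL41, 2 and 8 for MRPS34 and none for MRPL16. Of 18 cell cycle and replication genes 13 were higher and 2 lower, with 6 and 126 for PCNA, the sliding clamp of DNA replication, 1 and 33 for TYMS, 0 and 4 for CCNB1 and 3 and 107 for GINS2. Of 14 translation factors 6 were higher and 4 lower. EEF2 is given above, EIF4A1 had 1351 and 2491 (ratio 1.52, 1.42 to 1.62), EIF4G2 159 and 195 (0.857, 0.691 to 1.06) and the helicase EIF4A2 7 and 123.

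Of 13 aminoacyl-tRNA synthetase genes 8 were higher and 1 lower, with none for IARS2, 0 and 3 for IARS1, 0 and 15 for YARS1 and 1 and 43 for the lysyl-tRNA synthetase gene KARS1 (ratio 29.1, 4.95 to 1174). Of 14 proteasome and ubiquitin genes 7 were higher and 3 lower, with none for SQSTM1, 0 and 16 for PSMA4, 0 and 11 for PSMD11 and 1 and 15 for PSMC3. Of 10 endoplasmic reticulum genes 5 were higher and 1 lower. Beside CALR, HSPA5 had none, ATF6 0 and 50, and MANF 0 and 61, at least 14.7-fold higher (lower limit 11.6). Of 11 integrated stress genes 8 were higher and 1 lower, with 1 and 25 for SLC7A5, none for EIF2AK4, and 0 and 1 for both ASNS and CEBPB. Of 7 oxidative stress genes 5 were higher and none lower, with TALDO1 as above, none for ME1, 2 and 33 for TKT and 0 and 9 for GCLC. Of 10 sterol and fatty acid synthesis genes 5 were higher, none lower and 5 without counts, with 1 and 30 for the fatty acid synthase gene FASN, 0 and 46 for SC5D, 211 and 332 for FDFT1 and none for DHCR7. Of 17 interferon and innate sensing genes 6 were higher, none lower and 11 without counts, with 1 and 21 for ADAR, an RNA-editing enzyme, and none for ZC3HAV1 and EIF2AK2. Of 10 histone genes 6 were higher and 1 lower, with 0 and 1 for H2BC18, 0 and 2 for H1-2, 2 and 8 for H1-4 and 1 and 15 for H2AC15. Of 8 glycolysis genes 3 were higher, 1 lower and 4 without counts. ALDOA had 766 and 1735 (ratio 1.27, 1.17 to 1.39), LDHA 160 and 405 (1.41, 1.17 to 1.70), and PGK1 and HK2 none. Of 6 p53 target genes 2 were higher, 1 lower and 3 without counts. DDB2 had 37 and 53 (ratio 0.811, 0.523 to 1.27), BBC3 0 and 25, at least 4.12-fold higher (lower limit 3.11), BTG2 1 and 14 (ratio 9.15, 1.39 to 387) and FAS none.

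In some groups many genes had no extended count. Of 20 cytosolic ribosomal protein genes 11 had none in either library, 6 had a higher and 3 a lower share in transgenic cells. RPL37A had 0 and 62, at least 19.6-fold higher (lower limit 15.5), while RPS16 had 1211 and 1678, shares of 11.3% and 11.2%. For 5 of 7 nonsense-mediated decay genes there was none, among them RNPS1, XRN1 and CASC3, and MAGOH had 0 and 1. The same held for 6 of 11 termination, recycling and rescue genes, among them ASCC1, while DENR had 684 and 744, shares of 29.2% and 28.4%. ETF1, the release factor that recognises stop codons, had 0 and 9 extended counts beside 1793 and 2326 coding counts (at least 2.30-fold higher, lower limit 1.52), and ABCE1, which recycles ribosomes after termination, had 0 and 8 beside 4027 and 6577 (at least 1.63-fold higher, lower limit 1.04). GSPT1 was not among the genes at the count minimum. The length of the extended regions is not given, so the size of a gene's share, and with it the classes by share and differences in percentage points, depends on a length that is unknown. Of the 25 genes listed in advance as reported readthrough genes, 2 were measured. SACM1L had 9 and 12 extended counts (1.56% and 1.36%) and ACP2 had 68 and 129.

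Among the 8 genes with the largest differences in percentage points upward were SRP68, TLCD3A, HSPA9, COG6, DBNDD2, RAB40C and MARCKSL1. MARCKSL1, a membrane-associated actin-regulating protein, had 3 extended counts in HEK293T and 754 in transgenic cells beside 2207 and 3259 coding counts, shares of 0.136% and 18.8% (ratio 138, 47.2 to 673). The others named here had few coding counts, such as 89 and 90 for SRP68 and 70 and 69 for HSPA9. Each value is of 1 TAG-ending transcript of the gene. It does not describe other isoforms, which may end in other stop codons. SRP68, a signal recognition particle subunit, had a share of 49.4% in HEK293T and 75.3% in transgenic cells, TLCD3A 22.8% and 48.1%, HSPA9 32.0% and 55.2%, and COG6 10.6% and 30.3%. DBNDD2 had 0 and 25 extended counts (at least 4.78-fold higher, lower limit 3.61) and RAB40C 0 and 10 (at least 4.36-fold higher, lower limit 2.93). On the other side, CCDC25 had 55.5% in HEK293T and 31.0% in transgenic cells, KREMEN1 40.7% and 18.5%, RSAD1 45.1% and 25.3%, TMEM132A 34.6% and 15.5%, IPO7 24.8% and 9.23%, NPRL2 30.4% and 16.5%, and CDR1 15.5% and 2.31%. The mitochondrial ribosomal protein gene MRPS14 had 244 and 104 extended counts, shares of 33.2% and 11.4% and a ratio of 0.344 (0.271 to 0.435). The counting interval of NPRL2, 0.253 to 1.16, included equal shares.

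The second comparison was of footprint levels in coding regions, scaled to each library's coding total. Histone genes as a list were lower in transgenic cells, with a median log2 ratio of -0.49. The linker histone gene H1-2 had 53361 coding counts in HEK293T and 35834 in transgenic cells, a log2 ratio of -1.07 (-1.09 to -1.05). The homeobox gene NKX2-3 was at -2.44 (-2.73 to -2.26). The carboxypeptidase gene CPA4 was higher, at 1.62 (1.29 to 2.17), and genes of the integrated stress response were slightly higher, with a median of 0.35. Most genes were close, with r = 0.983 and rho = 0.982 across 4086 genes, which are not independent replicates. The median log2 ratio, transgenic over HEK293T, was 0.05 and the middle 95% of genes lay between -0.67 and 0.61. By the fixed rule of size, 28 of 8365 transcripts were at least 2-fold higher in transgenic cells and 49 at least 2-fold lower. With 1 transcript per gene these were 12 and 33 of 4086 genes. The interval lay wholly beyond 2-fold for 3 higher genes, CPA4, DYNLT1 and GPRC5A, and for 14 lower ones.

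The 12 highest genes had mostly low counts. CPA4 had 54 coding counts in HEK293T and 251 in transgenic cells. GPRC5A, an orphan G protein-coupled receptor, had 2384 and 8008 (log2 interval 1.18 to 1.32), and DYNLT1, a dynein light chain, 160 and 551 (1.26, 1.03 to 1.55). HEMK2, also known as N6AMT1, a methyltransferase that acts on the release factor ETF1, had 33 and 124 (1.27, 0.85 to 2.01). The others were LRRC24 (1.31), GTF3C3 (1.22), SYNPO (1.20), HOMER1 (1.03), the creatine kinase CKM (1.03), CYB561 (1.08), ZNF667 with 26 and 88 counts, and the growth factor BMP2 with 123 and 357. Among the 12 lowest identifiers, NKX2-3 had 754 and 189 coding counts, the growth factor GDF7 2234 and 951 (-1.72), SOX1, a neural transcription factor, 453 and 260 (-1.27), and the BMP antagonist CHRDL1 93 and 23 (-2.16). The cadherin genes PCDH15, with 113 and 17 (-2.73), and FAT3, with 265 and 79 (-2.13), also belonged to this end. So did CASQ2 (-1.78), the complex I assembly factor NDUFAF2 (-1.58), GLRX5 (-1.41) and ENSG00000268089 (-1.77), which has no symbol in the table. The remaining pair were identifiers that both carry the histone H4 symbol H4C13, at -2.04 and -2.03. Several genes encode the same H4 protein, so the symbol and the split of reads are uncertain.

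Of the 24 gene lists, 18 had at least 5 measured members, and the median of 5 of these lay outside the middle 95% of 10000 random lists matched on level. With lists of unrelated genes 0.9 would be expected, but members of a list can move together with any difference in culture or preparation, so these percentiles do not separate the cell lines from the libraries. Histone genes were lower in transgenic cells. The median over 10 measured members was -0.49, below all matched lists (random range -0.13 to 0.23). Of these, 9 were lower and 1 higher, and 2 were at least 2-fold lower. H4C13 stood at -2.04 and the linker histones H1-2 at -1.07 and H1-4 at -0.60, H2AC15 at -0.40 and H3C1 at -0.48. A second identifier carries the symbol H2AC15, at -0.43. H2BC18 was at -0.08. Of the remaining members, H1-5 was at -0.68, MACROH2A1 at -0.50 and H2AZ2 at -0.10. The member with the symbol H3-3A was at 0.51. Another gene encodes the same protein, so this symbol is uncertain. Mitochondrial ribosomal protein genes had a median of -0.18 (random range -0.05 to 0.18, percentile 0.01), 18 lower and 10 higher. By 1.5-fold or more 3 were lower, MRPL41 at -0.71, MRPL51 at -0.94 and MRPL36 at -1.08, and 1 was higher. The abundant members MRPL12, MRPL16 and MRPS34 were at -0.33, -0.17 and -0.41. Cytosolic ribosomal protein genes had a median of -0.09 (percentile 1.63), 15 lower and 5 higher, with RPS7 at -0.23 and RPL29 at 0.85. Its percentile was 4.31 when the transcripts of a gene were summed and 2.63 at a minimum of 300 counts, inside the random range.

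Genes of the integrated stress and amino acid response had a median of 0.35 (random range -0.18 to 0.23, percentile 99.9), with 10 of 11 higher, none of them by 1.5-fold. The asparagine synthetase gene ASNS was at 0.44 (0.25 to 0.63), CEBPB at 0.48, CEBPG at 0.45 and the serine synthesis gene PSPH at 0.47. ATF4, the transcription factor of this response, was at -0.15 (-0.40 to 0.11) and SLC7A5, an amino acid transporter, at 0.12. All 6 measured p53 target genes were higher, with a median of 0.38 (percentile 99.3). The kinase gene PLK3 was at 0.94, ZMAT3 at 0.54, the pro-apoptotic BBC3 at 0.42, DDB2 at 0.34, FAS at 0.28 and BTG2 at 0.04. This percentile was 97.3 with summed transcripts and 96.4 at a minimum of 300 counts, inside the random range. Of the list members named, RPS16, H3C1, H3-3A, MRPL51, RPL29, CEBPG, PSPH, ATF4, ZMAT3 and PLK3 lie outside the naming rule and were chosen after their values were seen.

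**Figure D4:**
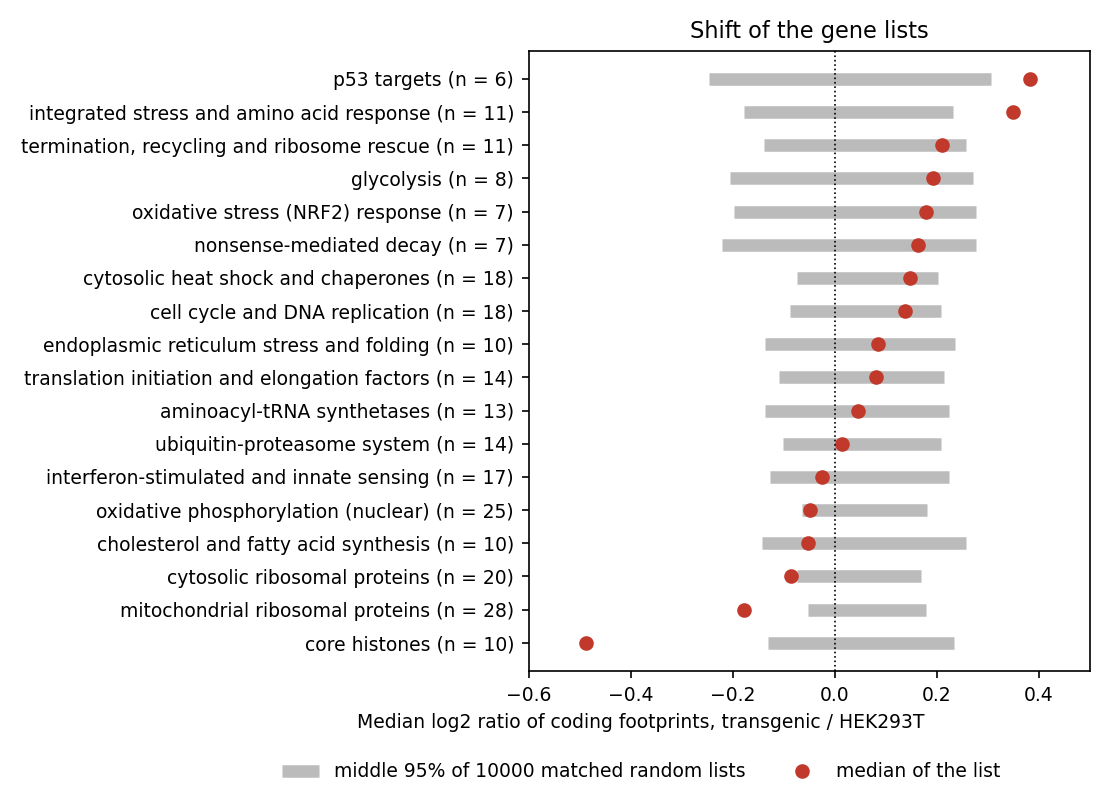
Median log2 ratio of coding footprints, transgenic over HEK293T, of each gene list with at least 5 measured members (points), with the middle 95% of 10000 random gene lists matched on level (grey bars). The lists of histones at -0.49, mitochondrial ribosomal proteins at -0.18 and cytosolic ribosomal proteins at -0.09 lie below their bars, and the integrated stress list at 0.35 and the p53 target list at 0.38 lie above theirs.

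The medians of the other 13 lists lay inside the random range. Termination, recycling and ribosome rescue genes had a median of 0.21 (percentile 92.5), with ABCE1 at 0.21 (0.15 to 0.27), ASCC1 at 0.59 and ETF1 at -0.12 (-0.21 to -0.03). Nonsense-mediated decay genes stood at 0.16, glycolysis genes at 0.19, oxidative stress genes at 0.18 and cytosolic chaperones at 0.15. Cell cycle and replication genes stood at 0.14 (percentile 82.7), endoplasmic reticulum folding genes at 0.09, translation factors at 0.08, aminoacyl-tRNA synthetases at 0.05 and proteasome genes at 0.01. Interferon and innate sensing genes were at -0.02, oxidative phosphorylation genes at -0.05 (percentile 5.51) and sterol and fatty acid synthesis genes at -0.05. CANX, a folding chaperone of the endoplasmic reticulum, was the member of these lists furthest below equality, at -1.26 (2241 and 1317 counts). Lists of other cell types had too few measured members for a median. Of 18 fibroblast markers 4 were measured, FBLN1 at -0.20, COL5A1 at -0.48, COL6A1 at -0.32 and COL6A2 at 0.20. Of 20 blood cell markers only CORO1A was measured (-0.54), of 18 epithelial and hepatic markers none, and of 23 neuronal and neural crest genes of HEK293 NES (0.11), SIX2 (-0.52) and LHX1 (0.28). Of the lysine metabolism and transport list KARS1 (0.05), GCDH (-0.01), SLC7A6 (0.25) and DHTKD1 (0.33) were measured.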

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

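The alternatives that leave out transcripts by combined share, and the one with 100 counts in each library, were chosen after seeing the data. The higher extended share in transgenic cells kept its direction under every alternative run, and its size depended on which transcripts entered. Against a ratio of 1.43, it was 1.40 with no minimum, 1.45 at a minimum of 300 counts, 1.31 for the mean of the transcripts' shares, 1.41 with 1 transcript per gene and 1.39 without the 10 transcripts with the most extended counts. It was 1.44 with 100 counts in each library, and 2.77, 5.63 and 6.81 without transcripts at a combined share of 10%, 3% and 1% or more. The transcripts left out at 10% or more hold most extended counts, and their own ratio was 1.13. The percentage of transcripts with a higher share, 83.5%, was 80.9% with no minimum, 85.5% at 300 counts, 79.7% with 1 transcript per gene, 88.5% under a 3% share and 85.0% with 100 counts in each library. The 77 transcripts at least 2-fold apart in coding level became 34 with a pseudocount of 5, 241 with no filter, 30 at 300 counts, 45 with 1 transcript per gene and 33 when the counting interval had to lie beyond 2-fold. The other scalings and a pseudocount of 0.2 left 77 to 96. The scalings moved all log2 ratios by -0.04, -0.04 and -0.03 (median of ratios, TMM and upper quartile), and lower transcripts outnumbered higher ones under each. Across transcripts, r moved from 0.980 to 0.989 with no filter and 0.978 at 300 counts, and rho from 0.978 to 0.987 and 0.967. The number of lists outside the random range moved from 5 to 3 at 300 counts and was 4 or 5 otherwise. The histone, mitochondrial ribosomal protein and integrated stress lists stayed outside under all 4 alternatives, and glycolysis went outside with summed transcripts (0.26, percentile 97.6). The 10 most abundant transcripts held 8.73% of HEK293T and 7.87% of transgenic coding counts, 13.2% and 11.8% with 1 transcript per gene, and 3.43% and 3.58% of the remainder once these were left out. For the other values that moved the cause was not tested. Leaving out positions within 15 nt of the stop codon was not run, as the table gives no positions, and with 1 library per group no library could be left out and no paired analysis was possible. Depth limits genes with few extended counts, where a count of 0 in HEK293T cells gives only a bound.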

Other observations

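The tests of depth, of a few transcripts, of passage over the TAG, of the transcripts at 10% or more and of the summed histone counts were chosen after the result was seen.

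Extended counts were spread over genes of every level. With the 4086 genes ranked by level and divided into 4 groups, 41.9% of the least abundant group had an extended count in transgenic cells and 24.9% in HEK293T cells, against 63.1% and 31.7% of the most abundant group. Among genes under a 3% combined share, the pooled share in transgenic cells was 0.483%, 0.511%, 0.427% and 0.347% from the least to the most abundant group, and in HEK293T cells 0.168%, 0.146%, 0.0982% and 0.0621%. The differences were 0.315, 0.364, 0.329 and 0.285 percentage points, and the ratios 2.88, 3.49, 4.35 and 5.58.

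In each library the 10 transcripts with its most extended counts held 29.0% of the extended counts in transgenic and 27.6% in HEK293T cells, and several had almost no coding footprints. A SERPINF1 transcript had 12 and 13 coding counts beside 9231 extended counts in HEK293T and 18318 in transgenic cells. A PGPEP1 transcript had 3 and 9 beside 9806 and 17254, and a KANK3 transcript 2 and 3 beside 4299 and 8194. Scaled to the coding totals, those of SERPINF1 were 1.41 times and those of KANK3 1.35 times as high in transgenic cells. In all, extended counts exceeded coding counts on 283 transcripts in HEK293T and 306 in transgenic cells.

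The higher extended share in the transgenic library was set against technical explanations. Depth is argued against by the 3952 transcripts with extended counts expected after thinning, against 1853. A few transcripts with most of the counts are argued against by the ratio of 5.63 (5.44 to 5.82) without transcripts at 3% or more. Reads spread over the genome whatever the expression are argued against by how often transcripts with under 10 coding counts had extended counts. In transgenic cells 4.81% (4.20 to 5.50) of these 4320 transcripts had them, against 51.5% at the minimum, and in HEK293T cells 3.26% had them. The 4320 include the 2408 transcripts with 0 in all 4 columns, which lower both of their percentages. The number of counts was not part of that test. The 4320 transcripts held 15912 extended counts in HEK293T and 31320 in transgenic cells, unscaled, a larger difference than depth alone would give. Extended counts were therefore also higher where coding footprints were few. At a combined share of 10% or more neither test decides: the ratio of 1.13 cannot be held to its bound of 2.81, which from 42.7% would pass 100%, and the scaled ratio of extended counts lay inside the range set for sequence shared with other transcribed regions, which may give near-equal counts, by its median of 1.15 (1.09 to 1.22), the test as first written, but outside it when pooled, at 1.32, a value added after the median was seen. More passage over the TAG in transgenic cells could give the 85.0% of 1657 genes under 3% that were higher. With 1 library per group it cannot be told apart from more RNA fragments not held by ribosomes. Extra extended counts followed coding counts (rho = 0.40 across genes), as both predict, and transcripts with other stop codons were not analysed here. Footprints at or near the stop codon could not be set apart from those further past it either, since positions are not given.

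Histone footprints were lower in the transgenic library. The sum over 13 histone identifiers was lower too, at a log2 ratio of -0.58 (-0.59 to -0.57), or -0.47 without both H4 identifiers. If each read was counted on 1 identifier, this argues against a split of reads among these identifiers alone that differs between libraries. The 2 identifiers named H4C13 had near-equal coding counts, 13587 and 13431 in HEK293T and 4653 and 4632 in transgenic cells. Reads may therefore be counted on both, and how they were assigned is not given. The sum would then hold the same reads more than once, and its interval would be too narrow. Only 10 of the 71 listed histone genes were measured. Reads assigned to near-identical copies that were not measured could lower the sum as well, so a split with those copies cannot be judged. Fewer cycling cells is argued against by the cell cycle and replication list, whose median lay at percentile 82.7 of matched lists, with 18 of 74 members measured. The list mixes genes of DNA replication with genes of other parts of the cycle. A smaller share of cells in S phase alone can therefore not be judged from its median. GC content and length were not tested, as sequences were not used here, and a difference between library preparations cannot be told apart from one between the cells. A biological difference between the lines stays open, untested.

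A hypothesis of lower coding footprints on genes with more extended counts was examined on the 104 genes with 20 or more extended counts and at least 8 times as many in transgenic cells after scaling. Their median log2 coding ratio was 0.01, against 0.09 (0.04 to 0.14) for sets matched on level from the 1914 genes with no extended counts, percentile 0.08. Of the 104 genes, 65 lay below the matched median. Over all 4086 genes the median was 0.05. Genes with extended counts that did not rise were not compared. A lower coding ratio of genes with extended counts in general could therefore give this percentile as well. The shift is small, 2 libraries cannot show whether it recurs, and a sequence bias shared by both properties could give it too.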
